A study of Homo sapiens with 3 samples.

How the data were processed

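Total RNA of 3 cultures was hybridised to NimbleGen single-colour (Cy3) arrays of HG18 transcripts, with 1 array each for latently infected CEM-SS, uninfected CEM-SS and H9/IIIB. The grouping follows the source names and characteristics in the labels. Per the labels' protocols, cells of passage 3 were grown in DMEM with serum and RNA was extracted with Trizol.

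The deposited file of each array gives an intensity per transcript on a linear scale for 45033 transcripts, and RMA is named in the submitters' processing notes. Its software and version are not given in the sources used here. RMA corrects background, normalizes arrays to common quantiles and summarises probes. The deposited table of the whole series gives an intensity for each of 135096 probes, 3 per transcript except for 2 transcripts, on linear scales that share a maximum of 62897 and have medians of 345.2, 355.6 and 355.9 for latent CEM-SS, uninfected CEM-SS and H9/IIIB. The transcript intensity lay within 0.01 (log2) of the median of its probes in that table for 60.7%, 79.9% and 79.8% of transcripts. How the probe values were scaled is not given in the sources used here. A column of standard errors in the deposited array files has an unstated scale and was not used. The files also hold a set of 5000 random-sequence control probes, which was left out of all comparisons and served as the background level. Median transcript intensity was 344.1, 331.9 and 333.3 in the same order, and the highest was 51092, 46158 and 48524. The number of arrays, 1 per group, limits the precision.

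Log2 of the transcript intensity was taken here, and a gene's value is the mean of the log2 values of its transcripts. The 45033 transcripts belong to 23620 gene identifiers in the files, of which 20230 were found in a RefSeq gene table that was used for current names only. That updated 6180 symbols, and others kept the name in the files. Because 24 symbols covered 2 identifiers each, 23596 genes remained. A single transcript stood for 11731 genes and several for 11865, with a median of 6 probes per gene. Coordinates are those of the files, on HG18, for the brightest transcript of a gene.

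With 1 array per group there are no residual degrees of freedom, so no p-value or standard error was computed. The rule of size counted a gene when the log2 values of the arrays differed by at least 1 and the brighter reading was at or above the median of its array over all genes. This was applied to latent against uninfected CEM-SS, H9/IIIB against uninfected CEM-SS and H9/IIIB against latent CEM-SS. Genes past the rule in the same direction from uninfected CEM-SS in both infected cultures, and genes of each array past it from both others, were counted as well. The overlap was set beside the product of the list sizes over the genes tested and beside 200 simulations of unchanged arrays with noise by 20 bins of level, both as set before the data were examined.

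The genes named are, per comparison and direction, the 10 with the largest difference among those past the rule whose transcripts all differ by at least 2-fold the same way, and the 5 largest for each count over 3 arrays. Members of the gene lists could be named as examples. Uncharacterised, open-reading-frame, pseudogene, olfactory receptor, Y-linked and XIST entries were passed over, with 98 genes in the last 2 groups. For the comparisons that use the latent array, further genes with agreeing probes were named, as were 2 immunoglobulin genes in H9/IIIB, and are identified in the text as chosen after their values were seen.

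A total of 34 gene lists covering T-cell identity and activation, antigen presentation, antiviral and HIV host factors, signalling, metabolism, stress, cell cycle and markers of other cell types was fixed before the data were examined. They hold 1001 measured genes, and 5 list symbols had no match. Each list's median difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. A median outside the range from the 2.5th to the 97.5th percentile is described as outside the random range, which describes these arrays and is not a test across samples. Of these lists, 1 is not reported here.

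Alternatives fixed in advance were the median of the probes in the series table, no filter on level or a filter at the 75th percentile, the brightest probe set of a gene, quantile normalization of the gene values, centring each array on its median, loess of the difference on level with a span of 0.3, and a 4-fold threshold. For lists, the median over members past the filter was added. Agreement of 3 probes and the median over all probes of a gene were added after the data were seen, as were the gene families of the closing section.

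The rule was tested on simulated data, 10 copies of the uninfected array of 23596 genes with known changes. Without unrelated probe values it called 50.0% of genes changed by 2-fold, 99.2% of those changed by 3-fold and 0.7% of unchanged genes. With 30% of probes replaced by unrelated values it called 78.0% of genes changed by 3-fold and 25.1% of unchanged genes, and with agreeing probes required these became 52.75% and 0.38%. Of 200 random lists of 30 genes, 2.0% fell outside the random range in the comparison of H9/IIIB with uninfected CEM-SS, and after a shift of 0.5 (log2) 89.5% lay above it. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.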

Results

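The expression of 23596 genes was measured in 3 human T-cell line cultures, each on 1 single-colour NimbleGen array. CEM-SS, a line derived from a T-cell leukaemia, was profiled without infection and after latent infection with HIV-1 Bru. Viral replication was represented by H9/IIIB, the T-cell lymphoma line H9 carrying a persistent HIV-1 LAI infection. Total RNA came from 10000000 cells at passage 3 in each culture. The question of the series was how transcript profiles differ between control cells, latently infected cells and cells with viral replication. Each group had 1 array, so the values carry no error and no test across samples was possible. A gene was counted as higher or lower when the arrays were at least 2-fold apart and the brighter reading reached the median of its array over all genes. Between H9/IIIB and either CEM-SS culture, cell line and infection state differed together. Against latent CEM-SS, the name given to the virus, LAI against Bru, differed as well.

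Median gene intensity was 293.6 in latent CEM-SS, 272.3 in uninfected CEM-SS and 265.9 in H9/IIIB, in linear units. Control probes of random sequence read 45.7, 31.3 and 29.4 on the same arrays. The share of genes at least 4-fold above these controls was 57.7%, 60.5% and 61.2%. A gene read near the control level is at background there, so the size of its difference is uncertain. The arrays differed in how well the 3 probes of a transcript moved together. The median SD of the 3 probe differences, on the log2 scale, was 0.49 between H9/IIIB and uninfected CEM-SS, 1.36 between latent and uninfected CEM-SS and 1.38 between H9/IIIB and latent CEM-SS. Across probes, which are not independent replicates, Pearson's r with uninfected CEM-SS was 0.709 for the latent array and 0.885 for H9/IIIB. Over the transcripts whose 3 probe differences lay within 2-fold of each other, 8131 of 45031 for the latent array and 23868 for H9/IIIB, r was 0.967 and 0.925. Both comparisons that use the latent array carry this disagreement, and the counts over all genes are therefore also given for genes with a transcript whose 3 probes agree. Agreement meant that all 3 were at least 2-fold apart in the same direction and lay within 4-fold of each other, a rule chosen after the probe values were seen.

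**Figure D1:**
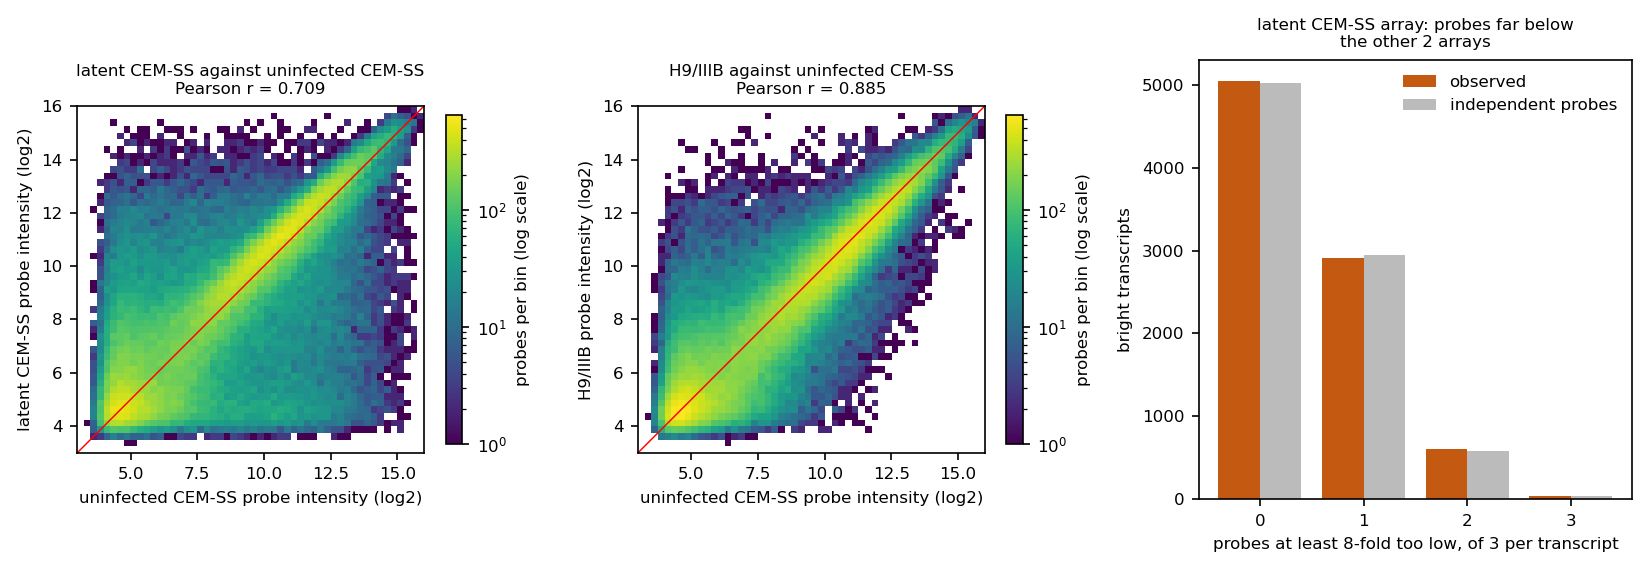
Log2 probe intensity on the latent CEM-SS array (left) and the H9/IIIB array (middle) against uninfected CEM-SS, with colour for the number of probes per bin and a red line of equality, and (right) the number of bright transcripts by how many of their 3 probes read at least 8-fold too low on the latent array. The latent array has a wide scatter (r = 0.709 against 0.885), and its far-off probes fall across transcripts as independent events would, with 36 transcripts having all 3 far off against 37.6 for independence.

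H9/IIIB cells carried high levels of genes that read low in uninfected CEM-SS. MYL4, a myosin light chain (HG18 chromosome 17, 42641712 to 42656044), read 22097 in H9/IIIB against 43.9, a log2 difference of 8.98. ACTA2, the smooth muscle actin, which read 140.8 in uninfected CEM-SS, was 7.93 higher, the surface glycoprotein THY1 7.77 higher, and CD74, the invariant chain of MHC class II (HG18 chromosome 5, 149761492 to 149772506), 7.37 higher. FOXN4 followed at 7.36, GPR15, a chemoattractant receptor that some HIV strains can use as a coreceptor, at 7.21, and the signalling adaptor TRAF1 at 7.00. The lymphoid tyrosine kinase BLK differed by 6.98 and the lymphoid transcription factor IKZF3 by 6.97, and IPCEF1, at 6.90, completed the 10 genes furthest above the control. In uninfected CEM-SS, FOXN4 read 20.1, IPCEF1 24.7 and BLK 26.6, below the random control of 31.3, and THY1 at 35.2 and IKZF3 at 36.7 were near it. The size and order of these differences are therefore uncertain. In the other direction, the genes furthest below uninfected CEM-SS were RASL10B at -5.22, the T-box factor TBX4 at -5.02, PLCH1, a phospholipase C, at -4.99, and the serpin SERPINB2 at -4.92. They were followed by PRSS21 at -4.86, the guanine nucleotide exchange factor VAV3 at -4.75, the BMP antagonist SOSTDC1 at -4.71, the amino-acid transaminase BCAT1 at -4.62, CHI3L2 at -4.53 and PELI2 at -4.52. Agreeing probes backed 7 of the 10 higher genes and 10 of the 10 lower genes. THY1, FOXN4 and TRAF1 had no transcript with agreeing probes, although all their probes were at least 4.11 higher. A backed gene needs only a single agreeing transcript. Over all transcripts, the probes of MYL4 ranged from 3.45 to 9.95 and those of IKZF3 from 3.04 to 8.08. Those of CD74, GPR15 and IPCEF1 also spread over more than 4-fold.

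**Figure D2:**
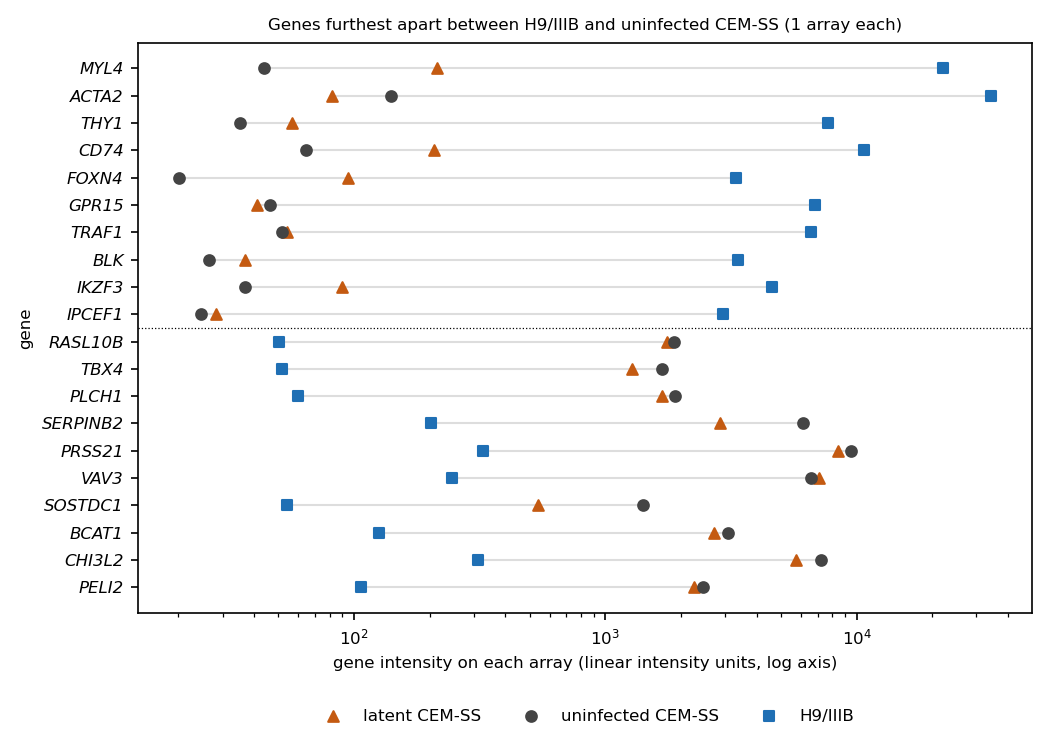
Linear gene intensity on a log axis for the 10 genes furthest above (top) and the 10 furthest below (bottom) uninfected CEM-SS in H9/IIIB, with a triangle for latent CEM-SS, a circle for uninfected CEM-SS and a square for H9/IIIB, 1 array each. MYL4 runs from 43.9 in uninfected CEM-SS to 22097 in H9/IIIB, and RASL10B from 1879 down to 50.5, with the latent culture close to uninfected CEM-SS in most of the lower genes.

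Among 12942 genes past the level filter, 1624 were at least 2-fold higher in H9/IIIB and 1653 lower, and 9665 (74.7%) lay within 2-fold. Agreeing probes backed 1084 of the higher genes (66.7%) and 1001 of the lower genes (60.6%). Of the 34 gene lists fixed before the data were examined, 9 had a median above the 97.5th percentile of random lists matched on level and 4 had a median below the 2.5th. Random lists would place 1.7 outside in both directions together. The fixed lists are not independent, since some share members such as TNF and LTA, so the excess over 1.7 does not measure chance.

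Antigen presentation by MHC class II stood furthest out. The median of its 15 measured members was 3.43 higher in H9/IIIB, 11 were at least 2-fold higher, 1 was within 2-fold and 3 were below the level filter. After CD74 at 7.37 came the peptide-binding chains HLA-DRB1 at 5.17, HLA-DQA1 at 5.03 and HLA-DQB1 at 4.23, although probes for such similar genes can share signal. In both CEM-SS cultures this list was mostly dark, with 14 of 15 members below the filter in the comparison between them.

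Genes of the NF-kappaB and AP-1 pathways were also higher in H9/IIIB. Of 35 measured members, 17 were at least 2-fold higher, 1 lower and 13 within 2-fold, and the list median was 0.89. TRAF1 at 7.00, the cytokine genes TNF at 5.50 and LTA at 3.93, and the apoptosis inhibitor BIRC3 at 4.48 led the list, while FOSL2, an AP-1 subunit, was at -2.91. LTA stood at -0.12 with its brightest probe set alone. The cytokine and chemokine list had a median of 0.48, with 7 of 38 members higher, 1 lower and 24 below the filter. The chemokine CCL5 stood at 6.10, IL16 at 3.92 and the death ligand TNFSF10 at 3.13, while XCL2 was at -2.03.

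T-cell identity genes moved in both directions. The list of activated and mature T-cell genes had a median of 0.44, with 9 of 30 members higher, 2 lower and 12 below the filter. Its furthest members were the TNF receptors TNFRSF1B at 5.99 and TNFRSF9 at 5.13 and the Th1 transcription factor TBX21 at 4.98, against S1PR1, a receptor for lymphocyte egress, at -3.67. The list of the T-cell receptor complex and proximal signalling had a median of -0.35, with 9 of 30 lower, 5 higher and 13 within 2-fold. The costimulatory receptor CD28 was at -4.13, CD7 at -3.50 and CD4, the primary HIV receptor, at -1.52, while CD6 at 6.76, ICOS at 5.38 and CD5 at 5.19 were on the other side. Of the 16 thymocyte and T-ALL genes past the filter, 10 were lower and 0 higher, all 10 with agreeing probes. These included the leukaemia-associated transcription factors LYL1 at -4.41 and LMO2 at -3.98 and the V(D)J recombinase genes RAG2 at -4.40 and RAG1 at -3.92. The median over all 30 measured members of that list, -0.23, lay inside the range of random lists.

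Host factors that restrict HIV were higher in H9/IIIB as a group. The list median was 0.61, with 7 of 27 members at least 2-fold higher, 0 lower and 16 within 2-fold. SLFN11, which limits viral protein synthesis, was at 4.36, the cytidine deaminase APOBEC3G at 2.71 and the dNTPase SAMHD1 at 2.57. The interferon-stimulated list had a median of 0.31, with 10 of 42 higher, 2 lower and 22 within 2-fold. The RNA sensor IFIH1 led it at 3.94, GBP2 stood at 3.78 and IFI27 at 3.15, while RIGI, another RNA sensor, was at -1.45. Neither the list of HIV entry, transcription and assembly cofactors, with a median of 0.05, nor that of HIV silencing and chromatin regulators, with a median of 0.04, left the range of random lists. Of the 39 silencing regulators, 34 were within 2-fold.

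Further lists described metabolism and the cytoskeleton. Cytoskeleton, adhesion and migration genes had a median of 0.48, with 12 of 38 higher and 2 lower, led by the integrin chains ITGAL at 4.98 and ITGB7 at 3.38 and the nuclear lamin LMNA at 2.34. ITGA6, another integrin chain, was at -4.22. Heat shock genes had a median of 0.55 with 3 of 22 higher and 0 lower, led by HSPH1 at 3.77. Cholesterol genes had a median of 0.51, but 23 of 29 were within 2-fold, 3 were higher, including the synthase LSS at 1.30, and 2 were lower, FADS2 at -2.26 and TM7SF2 at -1.12. The list of the unfolded protein response and amino-acid stress had a median of -0.89, with 14 of 30 lower and 3 higher. The amino-acid stress genes SLC7A11 at -2.79, SESN2 and PSAT1 at -2.71 and TRIB3 at -2.60 were among the lower genes. The endoplasmic reticulum chaperone HSPA5 at 1.80 and CRELD2 at 2.32, both targets of the unfolded protein response, were higher. G2/M cell cycle genes had a median of -0.43 with 28 of 31 within 2-fold and 3 lower, NDC80 at -2.00 being furthest. Oxidative stress and metallothionein genes had a median of -0.41 with 4 of 25 lower, 4 higher and 15 within 2-fold.

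In the fixed lists, markers of other cell types were mostly dark in H9/IIIB and uninfected CEM-SS. Of 23 myeloid genes, 21 were below the filter. Of 18 B-cell genes, 14 were below it and 2 were higher in H9/IIIB, BLK at 6.98 and the coactivator POU2AF1 at 5.70. Outside that list, and chosen after their values were seen, the immunoglobulin kappa genes IGKV1-5 at 6.58 and IGKC at 5.82 were also higher, with agreeing probes, although such similar genes can share signal. The B-cell markers MS4A1 and PAX5 were below the filter. Among 22 cytotoxic and NK-cell genes, the pore-forming PRF1 at 3.71 and NKG7 at 2.84 were higher, and GZMA at -3.25 and CD244 at -3.19 were lower.

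**Figure D3:**
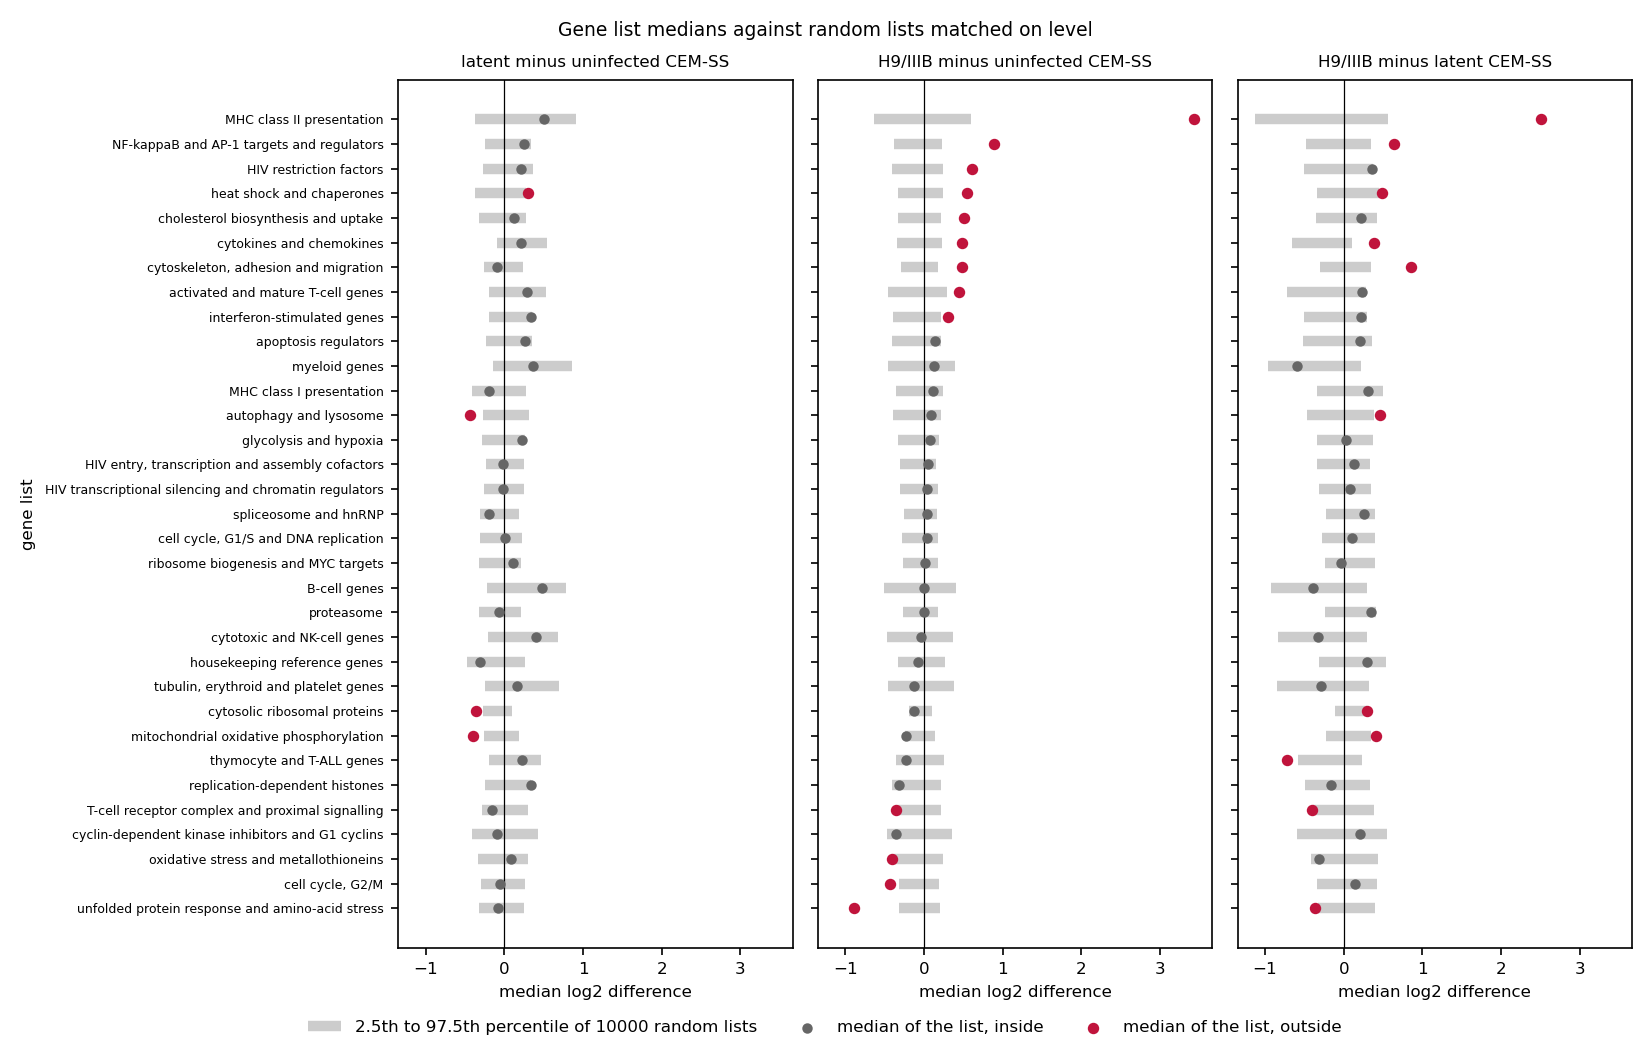
Median log2 difference of 33 of the 34 gene lists (points) in the 3 comparisons, with grey bars for the range from the 2.5th to the 97.5th percentile of 10000 random lists of the same size and level. Red points lie outside that range, and MHC class II presentation stands furthest out, at 3.43 in H9/IIIB against uninfected CEM-SS.

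Latent infection was compared with uninfected CEM-SS within the same cell line. Among genes with agreeing probes, the latent culture showed higher readings of TDRD12, a germ-cell tudor-domain gene (HG18 chromosome 19, 37899316 to 38004000), at 5.39, the secreted WNT ligand WNT10A at 4.78, the noncoding RNA AFAP1-AS1 at 4.40, CRNN at 4.31 and the adhesion molecule VCAM1 at 3.88. The amino-acid transporter SLC38A5 differed by 3.25, the growth factor receptor PDGFRB by 3.10 and the matrix proteoglycan VCAN by 3.03. USP7, a deubiquitinase (HG18 chromosome 16, 8894849 to 8964842), was at -8.96, the cell-surface protease ADAM10 at -6.08, the calcium-binding protein S100A4 at -4.97, thymidine kinase TK1 at -3.87, the lymphocyte receptor CD84 at -3.66 and cyclin CCND1 at -3.09. The IL-7 receptor chain IL7R was at -2.73 and the transcription factor MYCN at -2.26. Apart from USP7, which the rule fixed in advance also names, these genes were picked from those with agreeing probes after their values were seen. In S100A4, TK1, CCND1 and MYCN, which have several transcripts, at least 1 probe was on the other side of 0, and with the brightest probe set alone S100A4 stood at 0.50, TK1 at 0.50 and CCND1 at 0.07. In the latent culture USP7 read 33.3 and ADAM10 25.5, below the random control of 45.7. In uninfected CEM-SS they read 16555 and 1727. Bright transcripts with all 3 probes at least 8-fold low on the latent array were no more frequent than independent probes give, 36 against 37.6. The drop of USP7 is of this kind, and the probes of ADAM10 were all far low too, from -6.69 to -4.79. Neither drop can be told apart from chance agreement of unrelated probe values. In uninfected CEM-SS, TDRD12 read 22.1, AFAP1-AS1 25.5 and VCAM1 24.5, below the random control of 31.3. VCAN at 37.8, WNT10A at 47.2, PDGFRB at 50.3 and CRNN at 61.5 were less than 2-fold above it. The size of their differences is therefore uncertain.

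By the rule of size alone, 1213 of 12869 genes were higher in latent CEM-SS, 1853 were lower and 9803 (76.2%) lay within 2-fold. Agreeing probes backed 174 of the higher genes (14.3%) and 90 of the lower genes (4.9%). In simulated copies of the uninfected array with the estimated share of unrelated probe values, 3051.6 genes passed the same rule on average, and 48.8 passed it with agreeing probes. The 10 genes furthest above the control by the rule fixed in advance were ERN2 at 6.66, FLG at 6.52, GPR82 at 6.46, SSU72L6 at 6.41, TRPC7 at 6.38, SIGLEC11 at 6.33, GUCY2C at 6.32, PGAP3 at 6.24, SPACA9 at 6.18 and MIR663AHG at 6.03, of which 0 had agreeing probes. The furthest below were YARS1 at -9.09, USP7 at -8.96, FKBP1C at -8.23, PLEKHG4 at -7.89, LRRC37A3 at -7.76, ARMCX6 at -7.47, EXOSC6 at -7.40, NUTF2 at -7.33, PFDN2 at -7.21 and QRICH1 at -7.08, of which USP7 alone had agreeing probes. The probes of YARS1, a tyrosyl-tRNA synthetase, ranged from -9.34 to 0.03.

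**Figure D4:**
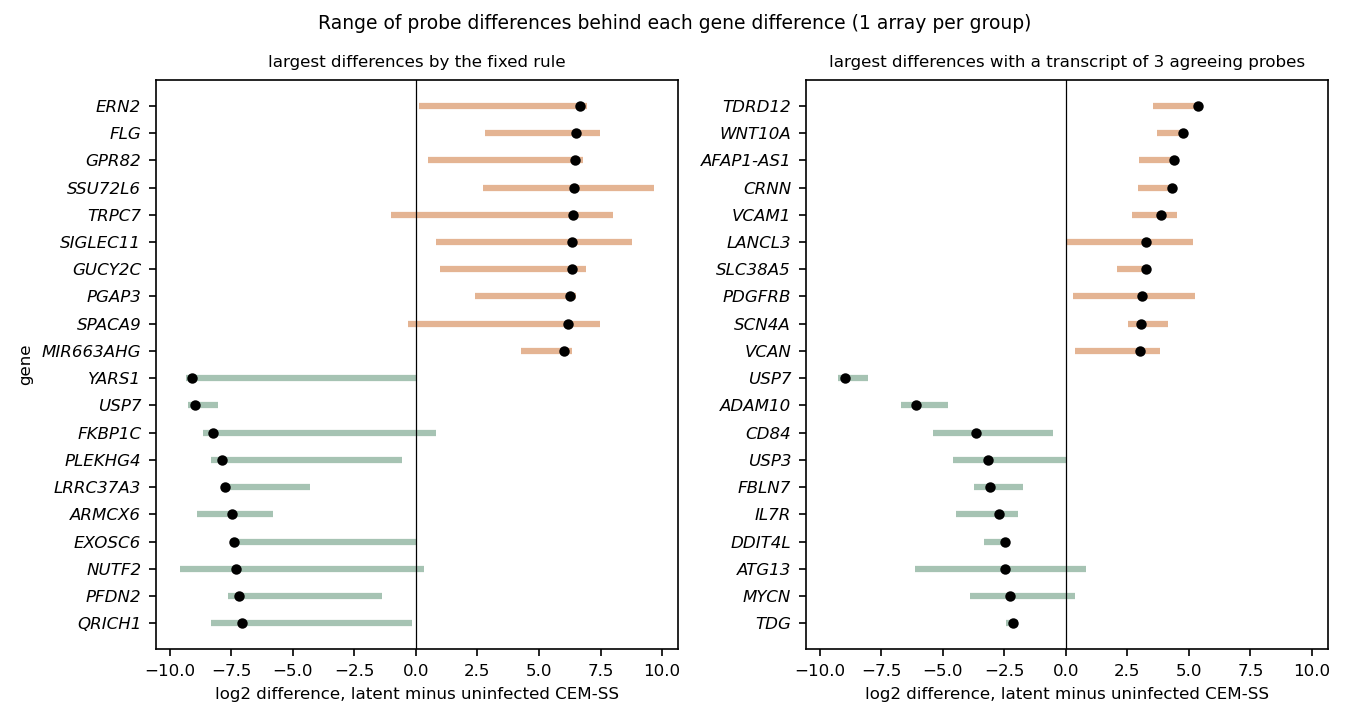
Log2 difference of latent minus uninfected CEM-SS for 10 genes in each direction, with a black point for the gene and a coloured bar from its lowest to its highest probe. On the left are the genes furthest out by the rule fixed in advance. On the right are the furthest that meet that rule's demand on all transcripts and have a transcript of 3 agreeing probes, which leaves out S100A4, TK1 and CCND1. Bars cross 0 in some genes of both panels, as in YARS1 on the left (-9.34 to 0.03) and MYCN on the right (-3.90 to 0.36), and the bar of USP7 does not (-9.27 to -8.04).

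Few gene lists stood apart between latent and uninfected CEM-SS, which ones depended on how probes were combined, and those named by the planned summary rested almost entirely on genes without agreeing probes. The heat shock list had a median of 0.30, above the random range, yet 5 of its 22 members were at least 2-fold lower, led by STIP1 at -4.79, and 1 was higher, with 0 backed by agreeing probes. Cytosolic ribosomal proteins had a median of -0.35 with 16 of 60 lower, 0 higher and 0 backed by agreeing probes. The mitochondrial oxidative phosphorylation list had a median of -0.39 with 12 of 46 lower, 1 higher and 1 backed, UQCRFS1 at -1.32, with probes from -5.39 to 0.17. The autophagy and lysosome list had a median of -0.44 with 4 of 31 lower, 1 higher, 24 within 2-fold and 0 backed, and this median was 0.10 when each gene was represented by its brightest probe set. Among HIV cofactors, CD4 was at -3.73 and the coreceptor CXCR4 at -2.52, neither with agreeing probes, and CD4 stood at 0.04 by the median of its probes and at 0.28 by its brightest probe set. The interferon-stimulated list, with a median of 0.34, lay inside the random range by the planned summary. Its members with agreeing probes were the antiviral GTPase MX1 at 2.41 and OAS3 at 1.66, and the RNA-activated kinase EIF2AK2 at -2.55, whose 9 probes ranged from -6.22 to 0.17 with a median of -1.18. NF-kappaB genes had a median of 0.25, also inside, with RELB at 1.78 and FOSL2 at 1.22 backed by agreeing probes. With the median over all probes of each gene, interferon-stimulated genes at 0.41, NF-kappaB genes at 0.40 and apoptosis regulators at 0.43 lay above the random range, heat shock genes at 0.30 and autophagy genes at -0.06 lay inside it, and ribosomal proteins and oxidative phosphorylation genes stayed below it.

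H9/IIIB was set against latent CEM-SS to compare replication with latency. Genes with agreeing probes that were higher in H9/IIIB included THY1 at 7.09, S100A4 at 6.95, TRAF1 at 6.93, the lymphocyte receptor CD96 at 6.62, glycophorin GYPC at 6.50 and the chemokine CCL5 at 6.36. On the lower side were the sodium channel SCN4A at -5.57, the carbonic anhydrase CA9 at -5.38, LYL1 at -5.32, the Hedgehog pathway factor GLI3 at -5.29 and S1PR1 at -5.29. These genes were chosen after their values were seen. S100A4 read 160.1 in latent CEM-SS, 5015 in uninfected CEM-SS and 19820 in H9/IIIB, and its probes here ranged from 1.24 to 10.26. With the brightest probe set alone, its difference between latent and uninfected CEM-SS was 0.50. By the rule fixed in advance, the furthest genes were FKBP1C at 8.98, USP7 at 8.72, ACTA2 at 8.72, YARS1 at 8.40 and PLEKHG4 at 7.80 above, and SSU72L6 at -7.15, SPACA9 at -7.02, TKTL1 at -6.79, TRPC7 at -6.42 and SLC22A12 at -6.26 below. Among the 10 genes this rule named in each direction, agreeing probes backed 1 higher gene, USP7, and 0 lower genes.

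Of 13386 genes past the filter, 2751 were higher in H9/IIIB than in latent CEM-SS and 2522 were lower, with agreeing probes in 516 (18.8%) and 815 (32.3%). Above the random range lay MHC class II presentation at 2.51, with 10 of 15 members higher and 5 of those backed by agreeing probes, cytoskeleton, adhesion and migration at 0.85, with 18 of 38 higher and 9 backed, NF-kappaB and AP-1 genes at 0.64, with 14 of 35 higher and 7 backed, and cytokines at 0.39, with 6 of 38 higher and 3 backed. Heat shock genes at 0.48, with 9 of 22 higher, oxidative phosphorylation genes at 0.41, with 10 of 46 higher, and ribosomal proteins at 0.30, with 15 of 60 higher, were above it too, each with 0 backed, as were autophagy genes at 0.46, with 10 of 31 higher and 2 backed. Ribosomal proteins turned to -0.07 with the brightest probe set. Below the range lay thymocyte and T-ALL genes at -0.72, with 8 of 30 lower, 7 of them backed, and 0 higher, the unfolded protein response list at -0.37 and the T-cell receptor list at -0.40. The T-cell receptor list held 11 higher and 6 lower members, 3 of each backed, and its median was 0.58 over members past the level filter. With the median over all probes, ribosomal proteins at -0.002, oxidative phosphorylation genes at 0.12, heat shock genes at 0.29 and the unfolded protein response list at -0.35 lay inside the range. Restriction factors at 0.35 and interferon-stimulated genes and activated and mature T-cell genes, both at 0.24, then lay above it, and cyclin-dependent kinase inhibitors and G1 cyclins went from 0.21, inside, to -0.88, below.

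Both infected cultures differed from uninfected CEM-SS in the same direction in a limited set of genes. BICRA, the glycosyltransferase gene MGAT3, the flagellin receptor TLR5, KIRREL3 and FLG were the furthest higher in both, at 4.36, 3.85, 3.81, 4.26 and 3.69 in H9/IIIB and at 4.63, 4.42, 5.44, 3.71 and 6.52 in the latent culture. RAG2 (HG18 chromosome 11, 36570068 to 36576362), NME4, the BMP antagonist NOG, GIMAP6 and ADGRG3 were the furthest lower in both, at -4.40, -4.01, -3.25, -2.97 and -2.78 in H9/IIIB and at -3.94, -3.82, -3.08, -3.20 and -3.16 in the latent culture. None of these genes had agreeing probes in the latent culture, and NME4 there stood at 0.06 by the median of its probes and at 0.18 by its brightest probe set. FLG in H9/IIIB stood at -0.01 by the median of its probes. Higher in both were 196 genes, of which 32 had agreeing probes in both comparisons, among them TNFRSF8, the CD30 receptor, at 2.10 in the latent culture and 3.13 in H9/IIIB and the galectin LGALS9 at 1.91 and 2.49. TNFRSF8 and LGALS9 were chosen after their values were seen. Lower in both were 298 genes, 26 with agreeing probes in both. Among the 12063 genes past the filter in both comparisons, 585 were higher in the latent culture and 913 in H9/IIIB, and 1853 and 1650 were lower. Independent lists of these sizes would share 44.3 and 253.5 genes. Simulated unchanged arrays, which share the uninfected control as the real ones do and were each given the noise of the latent comparison, shared 262.7 and 412.7 on average. Most of that noise belongs to the latent array, so the simulated counts are too high for H9/IIIB and the control, and how much of the overlap comes from the shared control stays open.

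Each array also stood apart from both others. H9/IIIB had 1137 genes higher and 1081 lower than both CEM-SS cultures, with agreeing probes in both comparisons for 343 and 434. By the rule for 3 arrays these were led by ACTA2, GPR15, THY1, TRAF1 and, at 6.78 from uninfected CEM-SS, CYTIP above and by RASL10B, PLCH1, VAV3, PRSS21 and TBX4 below. Latent CEM-SS had 851 genes higher and 1301 lower than both others, with agreeing probes for 72 and 35. SSU72L6, TRPC7, SPACA9, GPR82 and MIR663AHG led the higher set and USP7, YARS1, FKBP1C, PLEKHG4 and EXOSC6 the lower set.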

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

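The tests of the probe disagreement on the latent array were chosen only after that disagreement had been seen. Control probes of random sequence, which enter no comparison, read 45.7 in latent CEM-SS, above the 31.3 of uninfected CEM-SS, and 29.4 in H9/IIIB.

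On the latent array, 16.4% of 25779 probes from bright transcripts read at least 8-fold below their level on the other arrays, against 1.73% in the same kind of count for H9/IIIB. Of probes from dark transcripts, at most 32 on the other arrays, 16.8% read at least 8-fold higher on the latent array. A different RNA, through infection, other cells or a wrong label, would move the 3 probes of a transcript together. Yet 36 bright transcripts had all 3 far off on the low side where independent probes give 37.6, a ratio of 0.96. This argues against a different RNA behind the low probes of these transcripts, on which the other 2 arrays agreed within 2-fold. The count cannot show higher readings, changes under 8-fold or genes that differ between H9/IIIB and uninfected CEM-SS, so a different RNA stays open there. The share of far-off probes differed by a factor of 1.14 between the highest and lowest sixth of probe positions. Positions were pooled over transcripts of all lengths and not taken relative to an end, so loss of a transcript end stays open. Replacing an estimated 28.6% of H9/IIIB probes at random by unrelated values raised the median SD of their 3 probe differences from 0.485 to 1.354, close to the 1.359 of the latent array, so a random share of probes with values unrelated to their transcript is consistent with the pattern. What gave those probes such values, on the slide or in the making of the table, stays open and was not tested.

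The same replacement in copies of the uninfected array gave 3051.6 genes past the rule of size on average, with no gene changed, against 3066 observed between latent and uninfected CEM-SS. Unrelated probe values alone could therefore account for a count of that size, and most single genes named by that rule stay open. With agreeing probes the copies gave 48.8 genes on average and at most 61, against 264 observed, which argues against unrelated values as the whole account of those genes as a set. By direction the copies gave 19.0 higher and 29.8 lower genes against 174 and 90 observed. A single gene, above all a lower one, may therefore still be among the chance agreements. Bright transcripts with every probe at least 8-fold low on the latent array, as in USP7, numbered 36 against 37.6 for independent probes. The drop of USP7 therefore cannot be told apart from chance agreement, nor can that of ADAM10, whose probes ranged from -6.69 to -4.79. With 1 array per group, latent infection cannot be told apart from another difference between the 2 cultures behind the genes beyond the simulated count. A technical difference between the arrays that moves the probes of a transcript together stays open as well. Random control probes read 45.7 on the latent array and 31.3 on the uninfected array, and what this adds to the count was not tested.

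For the genes with agreeing probes at least 2-fold apart between H9/IIIB and uninfected CEM-SS, the presence of HIV-1 whatever the line would place the latent array nearer to H9/IIIB. Of those 2085 genes, it lay nearer to uninfected CEM-SS in 1699 (81.5%) and nearer to H9/IIIB in 386, which argues against presence of the virus as the account of the set. The cell line, H9 against CEM-SS, and productive infection cannot be told apart, because the series has 0 uninfected H9 arrays. Uninfected CEM-SS carried no virus, so a virus strain could differ only between H9/IIIB and latent CEM-SS, which was not tested.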

How the results depend on the processing

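Agreement of 3 probes and the median over all probes were chosen only after the data were seen. No paired analysis was possible because each group has 1 array, and leaving out an array would end its comparison. The 12 counts stayed within 1.5 times under loess, median centring, quantile normalization, the median over all probes and the probe medians of the series table. With the brightest probe set, 850 genes were lower in latent CEM-SS than in both others, and the other counts stayed within that bound. The cause was not tested, except that other filters and thresholds change how many genes can pass.

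With no filter on level, 3683 genes were higher in latent than in uninfected CEM-SS, 2663 were higher and 2944 lower in H9/IIIB than in uninfected CEM-SS, and 5111 were lower in H9/IIIB than in latent CEM-SS. Shared by both infected cultures were 791 higher and 625 lower genes, latent CEM-SS stood above both others in 2400 and H9/IIIB below both in 1901. With the filter at the 75th percentile, the higher and lower genes numbered 297 and 1115 for latent against uninfected CEM-SS, 699 and 587 for H9/IIIB against uninfected CEM-SS, 1566 and 974 for H9/IIIB against latent CEM-SS, 42 and 111 shared, 191 and 828 for latent CEM-SS apart from both others, and 505 and 378 for H9/IIIB apart. With the 4-fold threshold they numbered, in the same order, 456 and 809, 738 and 473, 1332 and 1018, 28 and 48, 370 and 608, and 511 and 322. With agreeing probes they numbered 174 and 90, 1001 lower only for H9/IIIB against uninfected CEM-SS since the 1084 higher genes stayed within 1.5 times, 516 and 815, 32 and 26, 72 and 35, and 343 and 434.

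Of list medians outside the random range, the T-cell receptor list in H9/IIIB against latent CEM-SS turned from -0.40 to 0.58 over members past the filter, which leaves out dark members. Ribosomal proteins in that comparison turned from 0.30 to -0.066 with the brightest probe set and -0.002 with the median over all probes. Autophagy genes in latent against uninfected CEM-SS turned from -0.44 to 0.098 with the brightest probe set. Among the named genes, the brightest probe set turned S100A4 to 0.502, TK1 to 0.501, CD4 to 0.279, NME4 to 0.177 and CCND1 to 0.07 in latent against uninfected CEM-SS, and LTA to -0.12 in H9/IIIB against uninfected CEM-SS. The median over all probes turned CD4 to 0.039 and NME4 to 0.06 in the latent comparison and FLG to -0.014 in H9/IIIB against uninfected CEM-SS. Over all alternatives, list medians stayed within 1 SD of the random lists in 566 cases, moved further in 144 and, among those outside the random range, changed sign in 4, and differences of named genes stayed within 1 SD of their probe differences in 979, moved further in 14 and changed sign in 9. That SD is wide where the latent array enters, 5.34 for YARS1 against uninfected CEM-SS, so only large shifts could exceed it. Genes with 1 transcript cannot move with the brightest probe set.

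The median over all genes was 0.157 in latent minus uninfected CEM-SS and -0.18 in H9/IIIB minus latent CEM-SS, and loess took it to 0.018 and -0.014. Higher genes made up 39.6% of calls between latent and uninfected CEM-SS, against 65.9% with agreeing probes, 57.3% with no filter, 56.5% with the brightest probe set and 21.0% with the 75th percentile filter. Between H9/IIIB and latent CEM-SS they made up 52.2%, against 61.7% with the 75th percentile filter and 38.8% with agreeing probes. Signal over background limits the values of dark genes, since 57.7% to 61.2% of genes read at least 4-fold above the random control.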

Other observations

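The gene families in this part were chosen only after the values had been seen, with all members taken by symbol. HOX genes, which encode homeodomain transcription factors, were higher in H9/IIIB than in uninfected CEM-SS. Of 39 measured HOX genes, 16 passed the level filter, 13 of those were at least 2-fold higher, 11 with agreeing probes, and 0 were lower. The family median was 1.21, with HOXC4 at 5.59 and HOXB9 at 3.07. The GIMAP genes, GTPases of lymphocytes, were lower in H9/IIIB in 7 of 7 members, 6 with agreeing probes, with a median of -2.99 and GIMAP5 at -3.53. In the latent culture their median against uninfected CEM-SS was -0.88, with 3 of 7 lower and 0 backed. Killer-cell immunoglobulin-like receptor genes had a median of -1.27, with 11 of 13 members past the filter lower and 8 backed, although these copies are so alike that probes can share signal. In the latent culture that family's median against uninfected CEM-SS was 0.70, with 0 members backed by agreeing probes.

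Zinc finger genes with ZNF symbols were lower in H9/IIIB on balance, with a median of -0.36 over 458 measured genes. At least 2-fold lower were 68 of the 295 past the filter and 15 were higher, with agreeing probes in 43 and 9. Keratin genes had a median of 0.42, and 11 of the 15 past the filter were higher, 0 lower and 5 backed by agreeing probes, with KRT81 at 5.16. The signs of these family medians between H9/IIIB and uninfected CEM-SS, and of the 2 given for the latent culture, were the same under each scaling and probe summary that was run. No cause was tested for any of them.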
